A study of Homo sapiens with 2 samples.

How the data were processed

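The series holds 2 libraries of human DNA, 1 of COT1 DNA and 1 of a painting probe for chromosome 11. COT1 DNA is the fraction of the human genome that reassociates fastest after melting and is sold to block repeats in hybridization. A painting probe is a pool of labelled DNA that stains a whole chromosome. Per the labels' protocols, both were made into Illumina libraries by end repair, adenylation, ligation of indexed adapters, selection of fragments on a gel and PCR, and were sequenced on a MiSeq. BWA, a read aligner, is named in the submitters' processing notes, with no version. The genome build, the repeat annotation, the peak caller, the treatment of reads that match several places and the treatment of PCR duplicates are not given in the sources used here.

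For COT1 DNA the authors deposited a table without column names. Each line has a repeat class, a family, a repeat name, 1 of 3 percent ranges that the file does not define, and 3 whole numbers. The first number was taken as the count of reads, since it is a whole number, often small, and exceeds the annotated bases for some satellites. The deposited counts were used as raw, with no normalization. The second was read as the annotated bases of that repeat in the reference, and the last as its number of annotated copies, since their ratio gives usual element lengths (261 bases for Alu). The percent ranges, and the lines of a name that stands in more than 1 class, were summed. For the chromosome 11 probe the authors deposited a list of peaks with start, end, length, summit, a count of tags, a score equal to 10 times the negative log10 of the p-value, and a fold enrichment, per the file headers. The peaks come from the 1 probe library. The background of the authors' fold is not given in the file header. Length equals end minus start plus 1, so positions count from 1 and include both ends. The authors' score takes 1 value, 3100, in 1860 peaks and does not order them, so peaks were ranked by tags, a choice made after the values were seen.

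Peak positions lay past the last RefSeq gene of GRCh38.p14 on 9 chromosomes, and the last peaks of chromosomes 9 (140434905), 21 (47990768) and 22 (51177520) ended beyond the published lengths of these chromosomes in GRCh38, so the positions are not those of that assembly. The build itself is not named, and no gene coordinates were set against the peaks. The planned comparisons of peaks with genes, exons, promoters, fixed gene lists, masked sequence and GC content were not run, because they need a genome and annotation of the same build. A ratio of repeat share between the libraries was not computed, since the COT1 table counts reads in repeats and the peak list gives no repeat content.

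The share of reads was computed per class, family, repeat name and repeat group, with exact Clopper-Pearson 95% intervals. The groups were fixed by name before the data were examined. Groups for what those names left over (ERVL, other L1, remaining satellites and remaining repeats) were added afterwards. Enrichment is the share of reads divided by the share of annotated repeat bases, so that 1 is the mean of all repeats, and its interval is an exact Poisson interval of the reads. It is relative to annotated repeats, not to the whole genome, because reads outside repeats are not in the table. Repeats with under 100 reads were left out of ranks of enrichment. The text names every fixed group, the 20 repeats with most reads, the 10 highest and the 5 lowest in enrichment, the 10 peaks with most tags on and off chromosome 11, the 5 widest peaks, the 5 longest peak-free stretches and the 5 highest and lowest 1 Mb windows, a rule set before the data were examined. Further repeats named as examples of a group were chosen after their values were seen.

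Peaks per Mb were computed over the span from the first to the last peak of each sequence, because chromosome lengths are not in the file, with exact Poisson intervals. Chromosome Y entered the totals and the median over other sequences but is not listed on its own. Coverage along chromosome 11 is the percent of bases under peaks in 1 Mb windows. Windows that touch the widest peak-free stretch, and the last window, which is incomplete, were left out of summaries. Correlations used two-sided permutation tests with 100000 permutations, and peak spacing was compared with 1000 random placements. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated counts for 762 repeats, 95.9% of the enrichment intervals held the true value.

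There is 1 library per group, so no value has a replicate error and no test between the libraries was possible. Depth was 20291978 reads in repeats for COT1 DNA and 4646529 tags in peaks for the probe. Reads or tags outside these features are not in the files. All intervals cover counting error only, and PCR copies make reads less independent than the intervals assume. The alternatives tried were filters on low counts, other quantities, the file's own classes, stricter peak sets, merged peaks and other window sizes.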

Results

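The composition of 2 DNA preparations used in an in situ proximity assay was measured by sequencing. COT1 DNA served as the repeated fraction and a chromosome 11 painting probe as the unique fraction. Each preparation was sequenced as 1 library, so the values below have counting error but no replicate error. The COT1 table held 20291978 reads in 1395 named repeats that together span 1448 annotated megabases. The chromosome 11 table held 33197 peaks that cover 12304899 bases and contain 4646529 tags.

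The first question was which repeats make up COT1 DNA. Alu elements, satellites and L1 elements together took 92.5% of the reads. Alu, a short interspersed element that spread in primates, took 33.2% of reads. Satellites, the tandem repeats of centromeres and other heterochromatin, took 32.5% from only 0.869% of the annotated bases. L1, the long interspersed element that is still active in humans, took 26.7%. Exact 95% intervals of these shares reach at most 0.0205 percentage points to either side. All other repeats took 7.53% of the reads from 42.6% of the annotated bases. Reads were concentrated in few names, since the 20 repeats with most reads held 74.5% of the total.

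Satellite reads came mainly from 3 groups. Alpha satellite, the repeat of human centromeres, held 3366156 reads, or 16.6% of the library, at 471 reads per annotated kb. The GAATG and CATTC pentamer satellites held 7.29% at 1995 reads per kb, and HSATII, a pericentromeric satellite related to these pentamers, held 6.79% at 4850 reads per kb. HSATII was thus 10.3 times as dense as alpha satellite. Beta satellite held 0.601% of reads at 97.2 reads per kb. The CATTC form had 3110 reads per kb (933451 reads) and its complement GAATG had 1237 (546136 reads), a ratio of 2.51. Relative to the mean of all repeats, 14.01 reads per kb, alpha satellite was enriched 33.6-fold, (GAATG)n 88.3-fold, (CATTC)n 222-fold and HSATII 346-fold.

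Satellites were not enriched alike. Of the 20 satellite names with at least 100 reads, 10 lay above the mean of all repeats and 10 below it. Gamma satellite, a GC-rich pericentromeric repeat, had 1.33 reads per kb (95% interval 1.24 to 1.44), 353 times fewer than alpha satellite. The group of HSATI and SATR had 12.5 reads per kb, but its members differed, with 705 for HSATI, 2.68 for SATR1 and 1.05 for SATR2. The group of SST1, ACRO1, TAR1, LSAU, MSR1, D20S16, CER and REP522 had 24.9 reads per kb, with 281 for ACRO1, 44.8 for CER and 2.12 for the subtelomeric TAR1. The remaining satellites had 771 reads per kb, of which SAR held 214381 of 214869 reads, on 1 annotated copy of 4775 bases. Densities of satellites depend on how many of their copies the reference holds, which was not analysed here.

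The 10 highest enrichments at 100 reads or more were SAR (3204-fold), HSATII, (CATTC)n, (GAATG)n, (G)n (70.6-fold), HSATI (50.3-fold), alpha satellite, (CACTC)n (28.6-fold), ACRO1 (20.05-fold) and (CGAAT)n (16.3-fold). Several rest on little annotated sequence, with 2903 bases for (G)n and 3066 bases for (CGAAT)n. The complement of (G)n, (C)n, had 1 read on 2974 bases. The 5 lowest at 100 reads or more were LTR78, Plat_L3, L3b, Tigger15a and MARNA, at enrichments from 0.0149 down to 0.0129. LTR78 belongs to the endogenous retroviruses, Plat_L3 and L3b to the CR1 family, and Tigger15a and MARNA to the DNA transposons. Of the 637 names with at least 100 reads, 102 lay above the mean of all repeats and 535 below it.

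Alu reads came from all 3 main branches. AluS, the middle branch in age, held 22.9% of the library at 24.7 reads per kb, AluJ, the oldest, held 5.71% at 15.9, and AluY, the youngest, held 4.22% at 21.8. AluS was therefore 1.55 times as dense as AluJ and 1.13 times as dense as AluY. The AluY group rests mainly on the name AluY, with 775417 of its 856511 reads at 22.5 reads per kb. Its other names with at least 100 reads ran from 11.7 (AluYk11) to 22.3 (AluYf5). All 17 AluS names with at least 100 reads lay above the mean of all repeats, as did 14 of 15 AluY names and 3 of 4 AluJ names. The monomeric and other Alu names had 9.54 reads per kb, with 0 of 4 above the mean of all repeats but 2 of 4 above the mean without satellites. Among single names, AluSx held 877204 reads, AluSx1 780408, AluY 775417, AluSz 685463 and AluJb 589663. AluSq2 (398866), AluSp (366972), AluSg (312832), AluSz6 (270532) and AluJr (264277) complete the Alu names among the 20 repeats with most reads.

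L1 reads came mostly from the young subfamilies. L1HS and L1PA, which arose in the primate lineage, held 21.8% of the library at 29.0 reads per kb. The older L1M and HAL1 elements held 2.03% at 1.30 reads per kb, although they have more annotated bases (21.9% against 10.6% of all repeat bases). The young group was 22.2 times as dense. L1PB, also primate, had 10.5 reads per kb, and the remaining L1 names had 19.1. Of 18 young L1 names with at least 100 reads, 11 lay above the mean of all repeats, against 0 of 76 such old names. Within L1PA, density was 42.4 reads per kb for L1PA2, 43.5 for L1PA3, 41.1 for L1PA4, 39.1 for L1PA5, 34.3 for L1PA6 and 30.01 for L1PA7. It was 17.6 for L1PA10, 8.70 for L1PA15 and 5.84 for L1PA17, a 7.45-fold difference between L1PA3 and L1PA17. The names that carry a letter or 2 numbers had 21.0 (L1PA8A) and 1.85 (L1PA15-16), the lowest of the L1PA names. L1HS, the youngest subfamily, had 32.8 reads per kb, and L1PA3 was 1.32 times as dense. L1 as a whole had an enrichment of 0.756, but 1.11 when satellites were left out of the mean. Alu had 1.57, or 2.30 without satellites. Without satellites, L1PB (0.750 to 1.10), SVA (0.728 to 1.07) and ribosomal RNA repeats (0.893 to 1.31) also turned from below to above the mean, and the other Alu names reached it (0.681 to 1.00087).

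**Figure D1:**
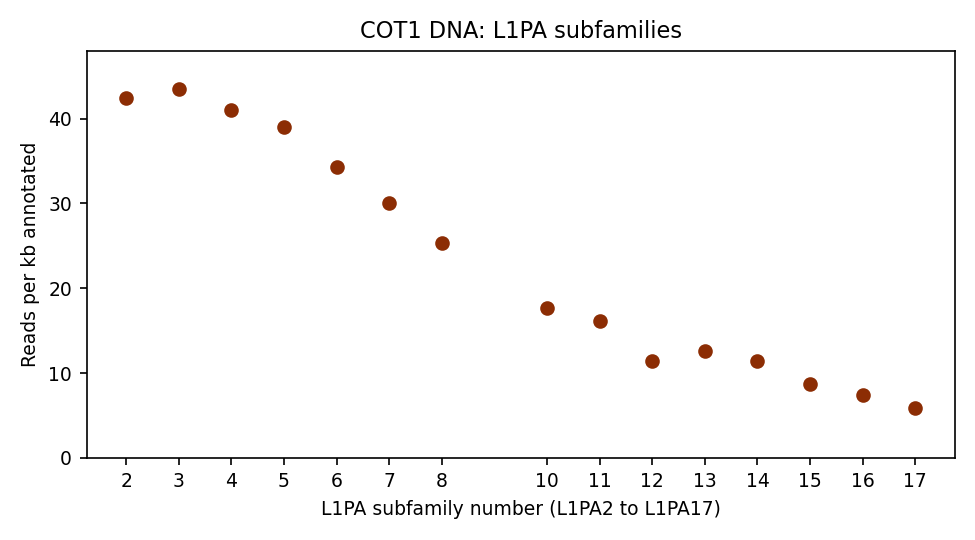
Reads per annotated kb of COT1 DNA (vertical axis) for the 15 L1PA subfamilies with a single number (horizontal axis; L1PA8A, at 21.0, and L1PA15-16, at 1.85, are not plotted), with exact Poisson 95% intervals that are mostly smaller than the points. Among these, density is 43.5 reads per kb in L1PA3 and 5.84 in L1PA17.

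MIR and L2, interspersed elements that predate the radiation of placental mammals, had 0.272 and 0.311 reads per kb, and Alu was 80.8 times as dense as MIR. DNA transposons had 1.14 reads per kb, and 0 of their 87 names with at least 100 reads lay above the mean of all repeats. Among endogenous retroviruses, ERVK had 8.49 reads per kb, ERVL-MaLR 5.90, ERV1 3.93 and ERVL 1.70. Most of their names with at least 100 reads lay below the mean of all repeats, with 5 of 26 ERVK, 7 of 50 ERVL-MaLR, 6 of 139 ERV1 and 2 of 51 ERVL names above it. Those above included LTR7 at 20.5, THE1B at 20.5 and LTR5_Hs at 18.2. SVA, a composite hominid element, had 10.2 reads per kb, with 0 of 6 names above the mean of all repeats but 4 of 6 above the mean without satellites. Ribosomal RNA repeats had 12.5 reads per kb, with 78.2 for the small subunit, 12.3 for the large subunit and 0.565 for 5S. Transfer RNA repeats had 1.34 (138 reads), other small RNA genes 1.48, simple repeats 3.88 and low-complexity sequence 3.33 reads per kb.

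**Figure D2:**
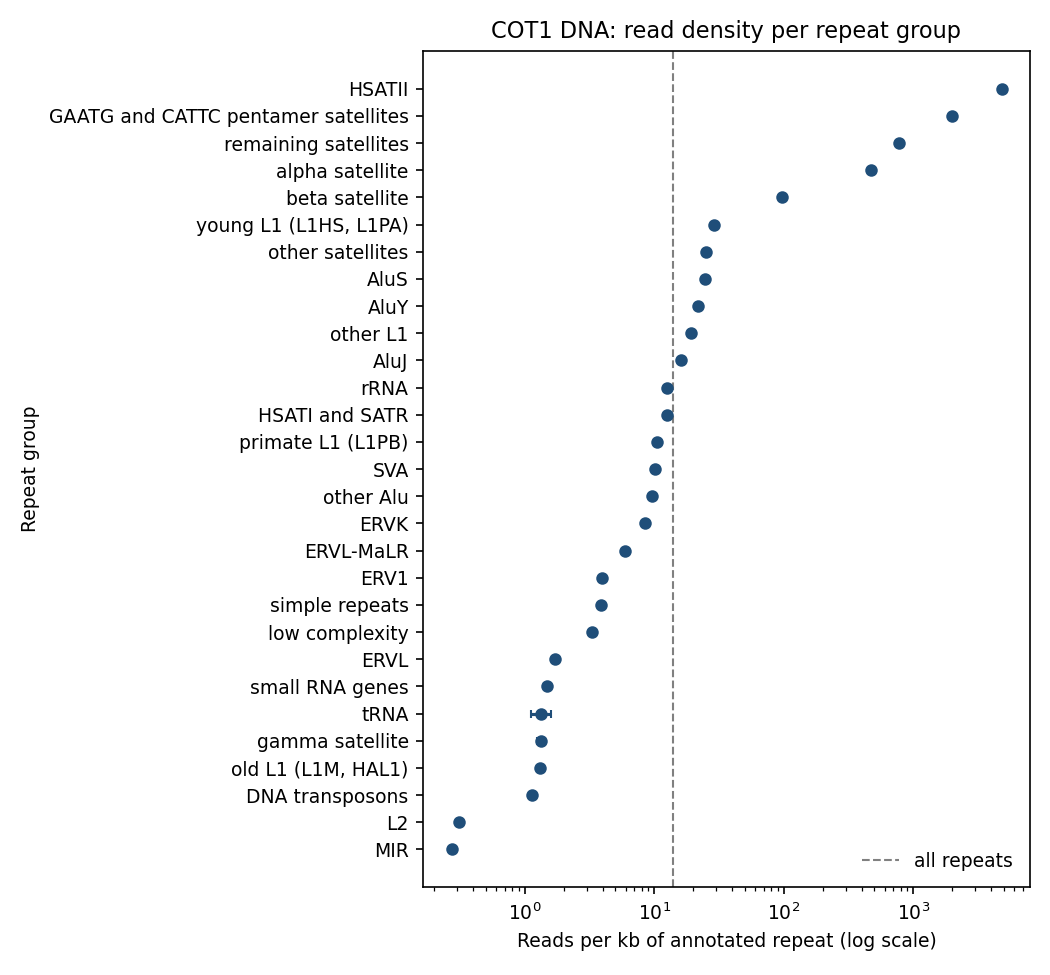
Reads per annotated kb of COT1 DNA (horizontal log axis) for each repeat group (vertical axis), with exact Poisson 95% intervals. The remaining repeats, at 0.256, are not plotted, while ERVL, other L1 and remaining satellites, groups added afterwards, are. The dashed line is the mean of all repeats, 14.01. Among the groups plotted, densities run from 0.272 in MIR to 4850 in HSATII.

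The second question was how specific the painting probe is for its chromosome. Chromosome 11 held 26321 of the 33197 peaks, or 79.3% (exact 95% interval 78.8 to 79.7). It held 88.2% of the bases under peaks and 95.6% of the tags in peaks. Probe DNA spread too thinly to form peaks is not counted, so these shares do not hold for the whole probe. There were 195 peaks per Mb on chromosome 11 (95% interval 193 to 198) against a median of 2.29 over the 24 other sequences, an 85.2-fold difference. The ratio was 275 among peaks with at least 34 tags and 33.1 among those at or above the median of the authors' fold. Among chromosomes 1 to 10, 12 to 22 and X, density ran from 1.22 per Mb on chromosome 19 (0.951 to 1.54) to 4.08 on chromosome 18 (3.64 to 4.56), and chromosome 11 was 47.8 times as dense as the highest of them. Chromosome 4 had 3.62 peaks per Mb, chromosome 5 had 3.26 and chromosome 10 had 3.13. Mitochondrial DNA held 4 peaks with 105 tags between bases 66 and 10892, or 369 peaks per Mb (101 to 946), an interval that includes the value of chromosome 11. Because the span is set by these same 4 peaks, that density is an upper value. Tags per kb of span were 9.70 for mitochondrial DNA and 32.9 for chromosome 11.

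**Figure D3:**
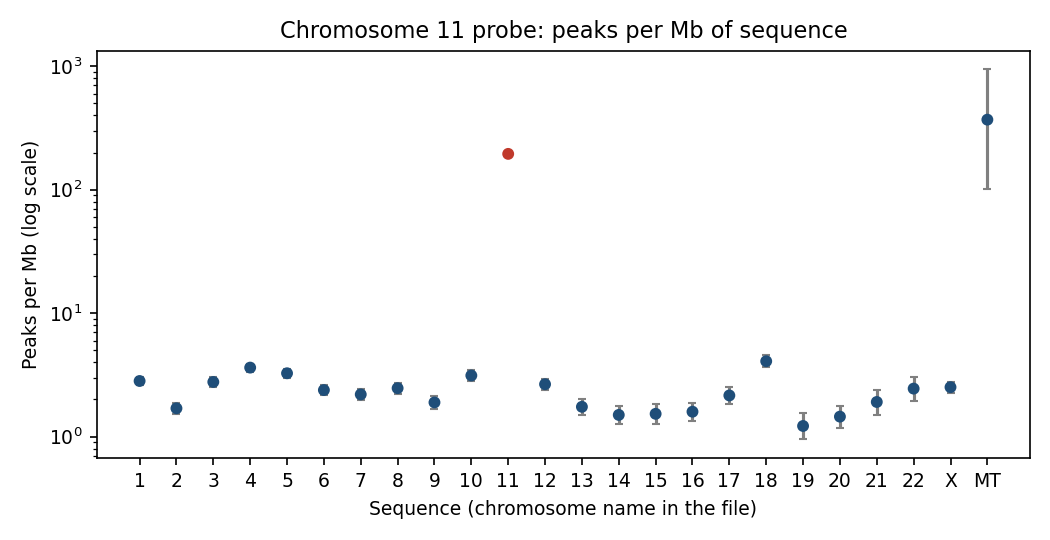
Peaks of the chromosome 11 probe per Mb (vertical log axis) for chromosomes 1 to 22, X and mitochondrial DNA (MT) on the horizontal axis, with exact Poisson 95% intervals; chromosome 11 is in red. Chromosome 11 stands at 195, and the other chromosomes lie between 1.22 and 4.08, while the mitochondrial value rests on 4 peaks.

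Peaks elsewhere were smaller than those on chromosome 11. The median peak held 43 tags on chromosome 11 (quartiles 20 and 107) and 13 elsewhere (9 and 27), and its median length was 375 against 184 bases. Peaks with at least 34 tags lay on chromosome 11 in 92.1% of cases, and those with at least 238 tags in 97.3%. The authors' fold enrichment ran the other way, with a median of 17.6 on chromosome 11 and 45.3 elsewhere. Chromosome 11 held 60.1% of the peaks at or above the median fold and 25.9% of those in the top 10% by fold. No fold exceeded 69.71, and 20.8% of peaks elsewhere lay within 0.05 of 66.23. A chromosome 11 peak with 125580 tags had a fold of 65.95, and a chromosome 17 peak with 682 tags had 64.96. High folds therefore do not rank peaks by tags. Outside chromosome 11 the most tags were 2026 in a peak of chromosome 12 at 14092198 to 14092505. The next were 1697 tags on chromosome 5 at 150851968 to 150852276, 1295 on chromosome 3 at 37507391 to 37507598 and 1210 on chromosome 4 at 32155789 to 32156048. The other 6 of the 10 lay on chromosomes 5, 10, 17 and X, with 682 to 930 tags each.

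The third question was how evenly the probe covers chromosome 11. Positions are those of the authors' file, whose build is not named. Peaks ran from base 79704 to base 134935736 and covered 8.05% of that span. The widest stretch without a peak was 3.13 Mb, from 51591617 to 54717798, in the part of the chromosome where the centromere lies. Before it there were 197 peaks per Mb (95% interval 193 to 201) and after it 202 (198 to 205), with 8.04% and 8.37% of bases covered. The other long peak-free stretches were 318 kb from 50780707, 157 kb from 96284762, 114 kb from 79855 and 59.1 kb from 87684795. Whether the reference lacks sequence in these or the widest stretch was not checked, since the build is not named. No read could align to missing sequence, so these stretches need not be absent from the probe. Leaving out the widest stretch, the median gap between peaks was 3.82 kb (quartiles 1.65 and 6.36), and 150 of 26319 gaps exceeded 20 kb.

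In 130 windows of 1 Mb the median covered share was 8.40% (quartiles 7.40 and 9.01), and the coefficient of variation was 15.04%. The lowest window was the first of the short arm, from 0 to 1 Mb, with 3.57% covered and 97 peaks. The next lowest were 50 to 51 Mb (4.82%), 89 to 90 Mb (5.68%), 1 to 2 Mb (5.80%) and 24 to 25 Mb (6.25%). The window from 50 to 51 Mb includes part of the peak-free stretch of 318 kb, and the first window includes that of 114 kb. The highest were 131 to 132 Mb (11.2%), 133 to 134 Mb (10.8%), 35 to 36 Mb (10.4%), 12 to 13 Mb (10.3%) and 45 to 46 Mb (10.3%).

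**Figure D4:**
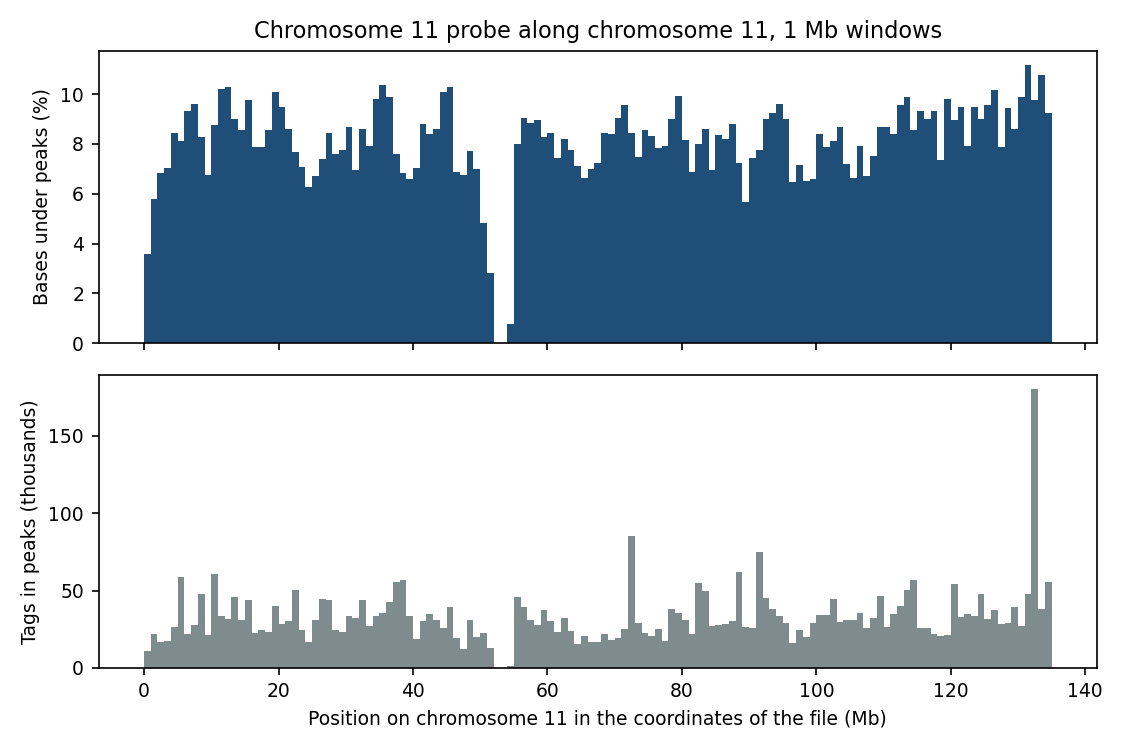
Percent of bases under peaks (upper panel) and tags in peaks, in units of 1000 (lower panel), in 1 Mb windows along chromosome 11 (horizontal axis, Mb in the coordinates of the file). The median coverage outside the peak-free stretch of 3.13 Mb is 8.40%, with 3.57% in the lowest window and 11.2% in the highest, while tags vary more between windows.

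Tags were less evenly spread than covered bases. Tags per window varied with a coefficient of 53.4%, or 38.6% without the single peak with most tags. The 263 peaks with most tags, 1% of those on chromosome 11, held 33.4% of its tags, and the top 10% held 67.9%. The peak with most tags, at 132714331 to 132715920, held 125580 tags, which is 2.83% of the chromosome's total and 69.7% of its window's. The next were 35947 tags at 91498397 to 91499013, 29211 at 5258940 to 5259639, 28046 at 72110739 to 72112146 and 28019 at 38409357 to 38410103. The remaining 5 of the 10 began at 22821619 (26847 tags), 102121870 (22729), 8836842 (21553), 132492130 (20011) and 15557830 (19933). The peak with 125580 tags is 1590 bases long, so many of its tags share a start position. PCR copies cannot be told from separate fragments in the peak list. The widest peaks were 2710 bases at 60866295, 2629 at 61075071, 2462 at 1016559, 2157 at 134609531 and 2087 at 1271365, and held 224, 226, 6619, 1030 and 214 tags.

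The comparison of the libraries that the design implies, repeated against unique DNA, could be made only side by side. COT1 DNA was described by reads in repeats, of which 32.5% were satellite, and the probe by peaks, of which 79.3% lay on its chromosome. The peak list does not give the repeat content of the probe.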

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

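Nothing here has replicates, so changes are judged against counting error, and for counts, densities and coefficients of variation against a factor of 1.5. No paired analysis was possible because each group has 1 library. Alternatives without satellites, by score, by fold, or without the peak with most tags, and the use of tags to rank peaks, were chosen after seeing the data. Of the 39 alternative values for the 2 libraries, 30 lie outside counting error or that factor, in part because the counting error of COT1 shares is so small. Without simple repeats and low complexity, satellites, Alu and L1 took 32.8%, 33.4% and 27.0% of reads, and with only names of at least 100 reads they took 32.6%, 33.2% and 26.8% (32.573, 33.211 and 26.767). By the file's class column satellites took 32.46%. Counted as annotated bases, the same groups are 0.869%, 21.2% and 35.4%, and as annotated copies 0.178%, 22.5% and 17.9%. Without satellites, Alu took 49.2% and L1 39.6% of the remaining reads; the enrichment of Alu was then 2.30, and that of L1 turned from 0.756, below the mean of all repeats, to 1.11, above it, because the mean fell from 14.01 to 9.54 reads per kb. L1PB (1.10), SVA (1.07) and ribosomal RNA (1.31) turned likewise, and other Alu names (1.00087) reached the mean within counting error. The 102 names above the mean were 109, 86 and 129 at 10 reads, at 1000 reads and without satellites. The share of peaks on chromosome 11 was 92.1% at 34 tags or more, 97.3% at 238 tags or more, 88.2% by bases, 95.6% by tags, 76.4% with peaks within 1 kb merged, 78.0% in the upper part by score (split at its median), 60.1% in the upper part by fold and 25.9% in the top 10% by fold. The density ratio of 85.2 rose to 275 at 34 tags or more, fell to 33.1 in the upper part by fold and was 88.8 over nuclear chromosomes. The coefficient of variation of coverage, 15.04%, was 8.75% in windows of 5 Mb and 53.4% for tags, or 38.6% without the peak with most tags; 250 kb windows, peaks with at least 34 tags and numbers of peaks gave 20.8%, 21.6% and 12.1%. The highest fold was 69.71, close to the commonest fold of 66.23, so the splits by fold do not rank peaks by tags. Beyond what each alternative leaves out or counts, the cause of these changes was not tested. Enrichment against the whole genome, and gene overlap, gene lists, masked sequence and GC content of peaks, were not run for want of reads outside repeats and of a genome of the same build. Depth limits repeats with few reads: 161 of the 1395 names had 0 reads, and 758 had under 100.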

Other observations

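The tests of subfamily order, annotated bases, copy length as the whole cause, tags per peak, even scatter, gene density and random spacing were chosen only after the result was seen; those of copy length in the highest percent range and of isolated peaks were set before.

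Of 34 pairs of simple repeats with complementary units and at least 100 reads each, 21 had densities in COT1 DNA within 1.5 times of each other, and the median ratio of higher to lower was 1.29. The pair of (CATTC)n and (GAATG)n differed by 2.51 times and the highest ratio was 2.84. The limit of 100 reads in each member tends to leave out pairs whose members differ. In 9 further pairs only 1 member reached it, and their ratios ran from 1.16 for (GAGAA)n and (TTCTC)n to 2943 for (G)n and (C)n. The next highest of these was 28.0 for (CAAG)n and (CTTG)n. Here (G)n had 2873 reads on 2903 annotated bases and (C)n, chosen after its value was seen, had 1 read on 2974. Complementary units are the 2 strands of the same repeat, so these ratios compare annotated loci, not different kinds of DNA.

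Among the 15 L1PA subfamilies with a single number, which follows their age, reads per kb fell with the number (Spearman's rho -0.986, Pearson's r -0.982, and r -0.982 without L1PA2 and L1PA17, each permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted 2.67e-05 for rho and 2e-05 for r over 8 relations; subfamilies are not independent replicates); with L1PA8A placed at 8 and L1PA15-16 between its numbers, rho was -0.982 over 17 names, but L1PA15-16 (1.85 reads per kb) lay below L1PA16 (7.37) and L1PA17 (5.84), and L1HS had 0.774 times the density of L1PA2. Annotated bases went with density (rho 0.579 with L1HS included). In a pair picked after the values were seen, L1PA16 has 3.31 times the bases of L1HS and 0.224 times its reads per kb (0.222 to 0.226). Their number thus does not set the order of these 2 names, but its part across the subfamilies stays open. Mean copy length also falls along the order (rho -0.857, permutation p = 7e-05, adjusted 0.00014) and goes with density (rho 0.861, permutation p = 0.00015, adjusted 0.00024). The partial rho of order and density given length was -0.946, which argues against length as the whole cause. In the highest percent range, where copies are short (means of 63.1 to 159 bases), rho was -0.279 (permutation p = 0.312, adjusted 0.357), inside the range set beforehand for length as a cause, but length there rises along the order (rho 0.943), so order and length would pull density in opposite directions, and density followed neither clearly (rho with length -0.182, permutation p = 0.515, adjusted 0.515). A part played by length therefore stays open; that length must not follow the order was set beforehand only for a result against length, and was extended to a result for it afterwards. Densities in the highest range were also lower, with 3.92 reads per kb in L1PA2 and 2.25 in L1PA17, against 42.4 and 5.84 over all ranges. That range held 12756 of 9593229 annotated bases in L1PA2 and 316693 of 3155384 in L1PA17. The mix of the undefined ranges thus differed between these subfamilies, and its part in the fall was not tested. A candidate explanation, that copies of young subfamilies are more alike and reassociate faster, was not tested, since no value of divergence was used here, and no biological explanation was tested.

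The authors' fold enrichment was higher outside chromosome 11, although tags per peak were fewer there (ratio of medians 0.302), which argues against stronger peaks as the reason. Matched on tags, the median fold on chromosome 11 was 0.308 times that elsewhere over all peaks, and 0.814 times (0.754 to 0.846, 95% range of 500 resamples) among peaks with no other peak within 10 kb, which were 227 peaks (0.862%) on chromosome 11 and 6263 (91.1%) elsewhere. The commonest fold, 66.23, was held within 0.05 by 20.8% of peaks elsewhere, and 10 kb divided by the commonest peak length, 151 bases, is 66.2. A background measured over a window of that size, which neighbouring peaks would raise, may account for part of the difference. Even among the isolated peaks the whole interval leaves a lower fold on chromosome 11, which neighbouring peaks within 10 kb do not account for. The interval also crosses the bound of 0.8 set beforehand, so how much of the difference such a background accounts for stays open, and no biological explanation was tested.

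Peaks outside chromosome 11 were not scattered evenly over the 22 chromosomes other than 11 and Y, since their variance was 25.9 times the Poisson expectation, against at most 2.94 in 10000 even draws. Chromosomes with more RefSeq protein-coding genes per Mb (gene numbers of GRCh38.p14 over the span of the peaks) had fewer peaks per Mb, with Spearman's rho -0.523 (permutation p = 0.0134, adjusted 0.0179 over the same 8 relations) and Pearson's r -0.441 (permutation p = 0.0376, adjusted 0.0501). The rho passed its bound of -0.5, but without chromosomes 17 and 19, farthest from the median gene density, r was -0.352 (permutation p = 0.126) and rho -0.472 (permutation p = 0.037), short of that bound, so the relation rests in part on those chromosomes and gene density stays open; the check without them was added after the result was seen. Sequence shared with chromosome 11, base composition and DNA of other chromosomes in the probe stay open, and neither they nor a biological explanation were tested.

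Gaps under 1 kb made up 15.8% of gaps between peaks on chromosome 11, against 18.9% to 20.3% in 1000 random placements of the same peaks on either side of the widest stretch, and the median gap was 3.82 kb against 3.12 to 3.25 kb. The random placements set no smallest distance between peaks, and how the authors' peak caller treated close peaks is not given. The shortage of short gaps therefore cannot tell a spacing of the probe DNA from the joining of close peaks.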
